A study of Mus musculus with 12 samples.

How the data were processed

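The series gives 1 table of FPKM values for 18740 genes in 12 placentas, computed by the authors. The submitters' processing notes name fastp 0.20.1, HISAT2 2.1.0, HTSeq 0.11.2, DESeq2 1.22.2 and the build GRCm39, without role or order. How the FPKM values were computed, with which annotation and after which filters, is not given in the sources used. The labels describe messenger RNA caught on poly-T beads and copied with random hexamers. No mitochondrially encoded gene is listed, and 2 columns of the table are empty.

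The deposited FPKM values were used on the scale log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the 12 placentas were kept (10913). A model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level (eBayes with trend). There were 7 comparisons: estradiol averaged over sexes, in females, in males, the male minus female difference of the estradiol effect, and male minus female averaged over treatments, in control and in estradiol placentas. The p-values were 2-sided and adjusted by the Benjamini-Hochberg method over all genes of a comparison, and 0.05 was the threshold. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

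Gene lists of placental layers, neighbouring tissues, immune cells and pathways (46) and 26 single genes were written down from general knowledge before the data were examined. A list needed at least 4 measured members, which left 43. They were tested with camera at a correlation of 0.01 between genes and adjusted over the 43. Camera ranks a list against all other genes, so a list with a median near 0 can be called up where most genes are lower. Each list was tested as well with a correlation estimated from the residuals, and with fry. Members were adjusted over their own list as a separate count.

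Genes were named by a fixed rule. Among genes with an adjusted p under 0.05, the 8 largest rises and the 8 largest falls with full separation of the groups within each sex were to be named. Where fewer than 3 genes passed, the 6 with the smallest p were named and said not to pass. Up to 4 members with the smallest p were named for a list described, and the 26 single genes were considered for each estradiol comparison. Symbols made of Gm and digits or ending in Rik were passed over.

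In each gene the deposited values are multiples of 1 step, so relative depth and whole reads could be recovered. Genes under 0.3 FPKM gave the steps, and whole reads were found for 100% of the 18740 genes within a tolerance of 0.02. They add up to between 37 and 40.4 M reads per library. The recovered reads served for voom and were not the source of the main values.

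The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean FPKM of at least 5 (6874 genes), median-of-ratios scaling, quantile normalization, no variance trend, robust variances, array weights, the replicate number as a block, treatment and number as a random block, a fit of the compared groups alone, each library left out in turn, adjusted p together with a log2 difference of at least 1, unadjusted p with the same limit, an estimated correlation and fry. Added after the data were seen were voom on recovered reads for genes and lists, the fit without control female 1 and estradiol male 3, yolk sac and decidual scores as covariates, and exact permutation of list means. The list alternatives for the sex comparisons within a treatment were run late, with the settings already fixed.

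A list score is the mean of the centred log2 values of its measured members in a library. Correlations between scores were taken on deviations from group means, with exact p from rearrangements within groups and Benjamini-Hochberg adjustment over the 7 relations. Chromosomes and gene types came from a GRCm38 annotation and no coordinates were used.

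Reads were simulated with each gene's own mean and spread within groups, and 94 to 99 genes changed at each fold. At a 2-fold change the fit recovered 85.1% of them for averaged estradiol, 69.1% in females, 66% in males and 42.4% for the interaction. For sex it was 89.4% averaged and 67% within control or estradiol placentas. At a 4-fold change these were 99%, 92.7%, 91.7%, 80.6%, 99% and 96.9%. Shares do not hold for fewer changed genes. Gene correlation was not simulated.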

Results

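Placental RNA was compared between control mice and mice exposed to high estradiol before birth, in 12 placentas that formed 4 groups of 3 (control or estradiol, female or male pups). The series title places the libraries in a study of low fetal weight after prenatal estradiol, so genes of the placental layers, vessels, hormones and nutrient transport were examined first. Differences are given on log2(FPKM + 1) with their standard error, and FPKM values as means ± SD. On this scale the fold of a gene near 1 FPKM is understated. The range beside a gene list is the lowest and highest adjusted p over its alternative settings. The labels say that the placentas were picked at random and do not name the dams, so the p-values measure the spread between these placentas.

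The sequenced placentas carried the sex their labels give. Ddx3y, a Y-linked RNA helicase, lay between 5.47 and 8.93 FPKM in the 6 male placentas and at most at 0.0323 FPKM in the 6 female ones. Eif2s3y lay between 1.61 and 3.37 FPKM against at most 0.0753, Kdm5d between 1.44 and 2.91 against at most 0.0542, and Uty between 0.749 and 1.3 against at most 0.00263. Xist, the X-linked RNA that would mark female placentas, is not listed in the table.

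The largest differences between single placentas lay in genes of neighbouring tissues. Afp, the fetal serum protein made by yolk sac endoderm, ranged from 15 FPKM in estradiol female 2 to 3000 FPKM in control female 1, with 2080 FPKM in estradiol male 3 and 1770 FPKM in estradiol male 1. The yolk sac score, the mean centred log2 value of its 20 measured genes, ran from -1.78 in estradiol female 2 to 2.75 in control female 1, a 23-fold range. In estradiol male 3 the decidual score was -1.10 and that of uterine natural killer cells -1.78, the lowest of the 12 libraries in both, and Prl8a2, a prolactin-family hormone of the decidua, stood at 352 FPKM against 948 to 2110 FPKM in the others. The first principal component held 35.3% of the variance and placed control female 1 (27.3) and estradiol male 3 (25.9) at one end. The second held 19.4% and set estradiol male 3 apart at -30. Libraries correlated with one another at r between 0.944 and 0.991 across genes.

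**Figure D1:**
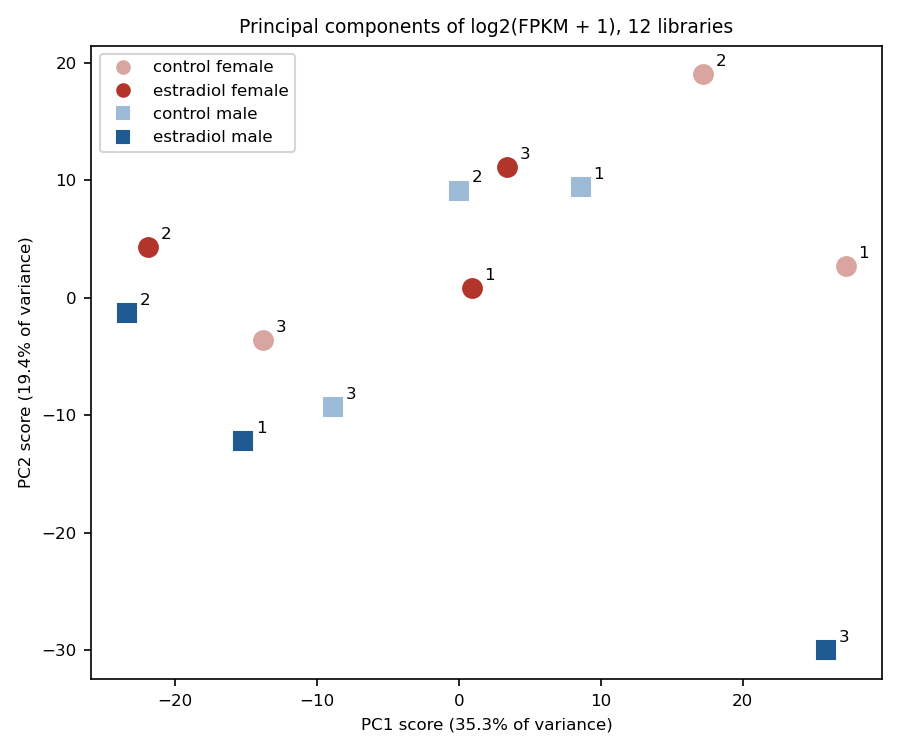
Principal components of log2(FPKM + 1) for 12 placental libraries, with the first component (35.3% of the variance) on the x axis and the second (19.4%) on the y axis, in score units; color and shape give treatment and sex, numerals the replicate. Estradiol male 3 lies apart at 25.9 and -30, and the 4 groups overlap.

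Across both sexes, Edn2 had the smallest p between estradiol and control placentas. Edn2, the vasoconstrictor peptide endothelin 2, stood at 17.5 ± 7.19 FPKM in 6 control and 5.52 ± 3.51 FPKM in 6 estradiol placentas (-1.63 ± 0.23), and Eln, the elastin of arterial walls, at 26.6 ± 5.69 against 12.3 ± 3.85 FPKM (-1.09 ± 0.18). Uggt1, the endoplasmic reticulum sensor of misfolded glycoproteins, was higher (28.3 ± 2.98 against 36.6 ± 1.96 FPKM, 0.37 ± 0.06), as were Aldh18a1, which makes the proline precursor (13.7 ± 0.588 against 17.9 ± 1.82 FPKM, 0.36 ± 0.06), and Enpp7, a sphingomyelinase (13.6 ± 2.86 against 23.8 ± 5.57 FPKM, 0.75 ± 0.13). Rnd1, a small GTPase that loosens the cytoskeleton, was lower (1.79 ± 0.51 against 0.82 ± 0.169 FPKM, -0.60 ± 0.10). In each of the 6 genes all 9 of 9 estradiol and control pairs within each sex went the same way, and they had the smallest p of 10913 genes tested. None passed in limma (adjusted p = 0.164 for each).

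No gene passed an adjusted p of 0.05 for estradiol averaged over the sexes by limma (count 0), nor by limma voom on recovered reads (0). At an unadjusted p under 0.05 limma found 1354 genes (221 higher, 1133 lower) and voom 1278, where about 546 are due to chance. That limma count was 868 without control female 1, 2241 without control female 3, 748 with treatment and number as a random block and 3687 with array weights. The array weights, whose search gave a convergence warning, passed 1110 genes at an adjusted p of 0.05, the replicate number as a block 1, yolk sac and decidual scores as covariates 1, and the fit without the 2 doubted libraries 3. The median difference of all genes was -0.08. With median-of-ratios scaling that median was -0.008 and the genes at unadjusted p divided into 524 higher and 472 lower, and with quantile normalization into 603 and 454. Both scalings centre the differences near 0, so they do not show which balance is right. A single library mattered: without estradiol male 3, 5 genes passed, without estradiol male 1, 2 genes, and without estradiol female 3 or estradiol male 2, 1 gene each.

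**Figure D2:**
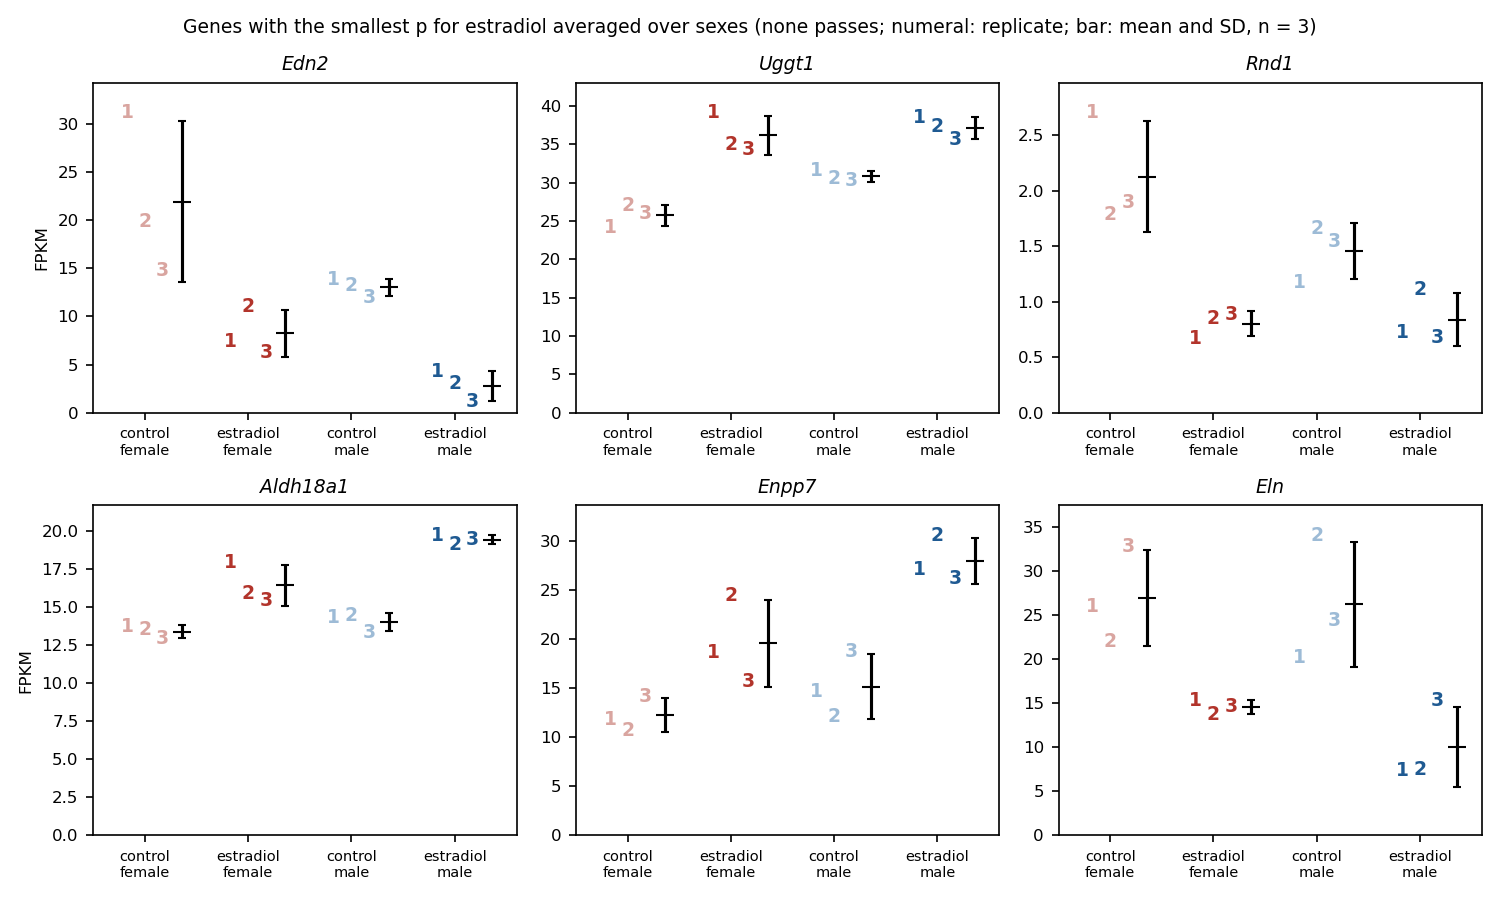
FPKM of the 6 genes with the smallest p for estradiol averaged over sexes (y axis, from 0) in the 4 groups (x axis), where numerals are single placentas by replicate and bars the mean and SD of 3. Edn2 means 17.5 FPKM in control and 5.52 FPKM in estradiol placentas, and none of the 6 passes (adjusted p = 0.164).

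Spongiotrophoblast genes, of the hormone-making cells between labyrinth and decidua, stood higher after estradiol, while glycogen trophoblast genes, of the same zone, were lower for 7 of 12 (mean -0.19, not called). Of 21 spongiotrophoblast genes 18 were higher (median 0.25, camera adjusted p = 1.81e-10, adjusted p = 0.385 with an estimated correlation, 2.68e-17 to 0.401 over 19 alternatives). Among them were Psg18 (901 ± 186 against 1310 ± 304 FPKM, 0.53 ± 0.15), Psg19 (421 ± 69 against 543 ± 90.8 FPKM) and the VEGF receptor gene Flt1 (173 ± 43.9 against 228 ± 22.7 FPKM, 0.43 ± 0.13). Pregnancy-specific glycoproteins, secreted immune modulators, were higher for 17 of 22 genes with their Ceacam relatives (median 0.17, adjusted p = 1.05e-06, adjusted p = 0.385 with an estimated correlation, 5.98e-12 to 0.403 over the alternatives), yet not in unison: Psg25 was higher (479 ± 131 against 723 ± 109 FPKM) and Psg22 lower (306 ± 102 against 160 ± 39.4 FPKM). Adjusted over the list alone, 3 of them were higher and 2 lower. The spongiotrophoblast list shares 9 genes with this list and 8 with the prolactin family, so the calls are not independent. How reads shared between close paralogs (prolactin, Psg, Ceacam, cathepsin and granzyme genes) were counted is not given in the sources used.

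The other trophoblast calls were weaker. Placental cathepsins of sinusoidal giant cells were higher for Cts3 (2790 ± 1050 against 4580 ± 1040 FPKM, 0.77 ± 0.21) and Ctsm (669 ± 192 against 1060 ± 285 FPKM, 0.68 ± 0.19), and 2 members passed adjusted over the list alone. The list had 5 of 9 genes higher (median 0.15), but 3 of 9 with a median of 0 after quantile normalization (adjusted p = 0.000713, adjusted p = 0.169 with an estimated correlation, 0.000228 to 0.401 over the alternatives). Prolactin-family genes were higher for 15 of 23 (median 0.13, adjusted p = 0.000812, adjusted p = 0.698 with an estimated correlation, 5.68e-07 to 0.727 over the alternatives). That call ended with median-of-ratios scaling (0.0849) and without estradiol female 2 (0.113) or estradiol male 2 (0.0839). Giant cell genes were higher for 5 of 9 (adjusted p = 0.0182, adjusted p = 0.385 with an estimated correlation, 0.00152 to 0.637 over the alternatives), a call that ended with median-of-ratios scaling (0.157) and without control female 2 (0.121), control male 2 (0.0679), estradiol female 2 (0.218), estradiol male 1 (0.0971) or estradiol male 2 (0.122). Glycogen trophoblast (adjusted p = 0.853), syncytiotrophoblast layer I (0.853), layer II (0.157) and labyrinth trophoblast progenitors (0.624) were not called, and the medians of the first 3 turned from below 0 to 0 or above with both other scalings. Within layer I, Tfrc, the transferrin receptor that takes up maternal iron, stood at 51.4 ± 23.6 FPKM in control and 18.3 ± 8.7 FPKM in estradiol placentas (-1.44 ± 0.40, limma adjusted p = 0.242).

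Protein folding and oxygen response genes were higher. Of 24 unfolded protein response genes 21 were higher (median 0.19, adjusted p = 8.2e-08, adjusted p = 0.344 with an estimated correlation, 1.89e-13 to 0.401 over the alternatives), among them Hyou1, a chaperone of the reticulum (71.9 ± 14.4 against 90.4 ± 15.6 FPKM), and Sesn2, a stress-induced brake on growth signalling (13.9 ± 2.23 against 17.8 ± 2.18 FPKM). Within groups the list score correlated with spongiotrophoblast at r = 0.84 (exact p = 0.00309). With this and the endothelium score as covariates its mean difference was 0.025 ± 0.071 instead of 0.163 ± 0.102. Xbp1, the transcription factor of this response, was lower (124 ± 9.66 against 111 ± 7.24 FPKM) in all 9 of 9 pairs of both sexes. Hypoxia and glycolysis genes were higher for 17 of 27 (median 0.05, adjusted p = 1.12e-06, adjusted p = 0.32 with an estimated correlation, 1.55e-10 to 0.401 over the alternatives), led by Ero1a, the oxidase that forms disulfide bonds (31.2 ± 3.01 against 40.4 ± 2.95 FPKM, 0.37 ± 0.07), and Vegfa, the vessel growth factor (28.3 ± 9.36 against 39.2 ± 4.57 FPKM, 0.50 ± 0.14). Glucose transport and glycogen genes had a median of 0 and 11 of 20 higher, which camera called up against the lower median of all genes (adjusted p = 0.00605, adjusted p = 0.445 with an estimated correlation, 0.000839 to 0.72 over the alternatives). Agl, the glycogen debranching enzyme, was higher in all pairs (4.62 ± 0.422 against 5.82 ± 0.61 FPKM).

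Natural killer and macrophage genes stood higher after estradiol averaged over sexes. Uterine natural killer cell genes, which include the granzymes and perforin, were higher for 7 of 8 (median 1.01, adjusted p = 1.13e-05, adjusted p = 0.385 with an estimated correlation, 2.67e-17 to 0.401 over the alternatives). Prf1 stood at 0.952 ± 0.418 against 3.7 ± 2.13 FPKM (1.10 ± 0.38). Gzme stood at 13.2 ± 5.45 against 32.4 ± 16.9 FPKM. Estradiol male 3, whose decidual score was the lowest, had a natural killer score of -1.78, while the other 5 estradiol placentas lay between 0.27 and 1.29 and the controls between -1.08 and 0.24. Within groups the natural killer score followed the decidual score at r = 0.95 (exact p = 0.00926, rho = 0.82 with exact p = 0.027, r = 0.86 without the 2 farthest, adjusted p = 0.013 over 7 relations). Macrophage and antigen presentation genes were higher for 11 of 16 (median 0.16, adjusted p = 1.37e-05, adjusted p = 0.305 with an estimated correlation, 1.5e-07 to 0.401 over the alternatives), among them the complement gene C1qa (7.48 ± 1.53 against 10.3 ± 2.14 FPKM). Decidual stroma (adjusted p = 0.0729) and neutrophil genes (adjusted p = 0.853, 6 of 6 lower, 5 of 6 with either other scaling) were not called, and the decidual median went from -0.02 to 0.05 with median-of-ratios scaling and 0.07 with quantile normalization.

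Averaged over sexes, endothelial genes were lower after estradiol for 19 of 20 with each scaling (median -0.35, adjusted p = 0.00605, adjusted p = 0.78 with an estimated correlation, 1.18e-05 to 0.78 over the alternatives). The call ended without estradiol male 1 (0.1). In males 13 of 20 were lower (mean -0.11, females -0.54) and not called (adjusted p = 0.812). Vwf, the clotting factor stored in endothelium, was lower in all 9 of 9 pairs of both sexes (3.83 ± 0.691 against 2.44 ± 0.406 FPKM, -0.49 ± 0.09) and passed adjusted over the list alone. Kdr, the VEGF receptor of endothelium, was lower too (15.3 ± 3.7 against 11.7 ± 3.32 FPKM, -0.36 ± 0.15). Pericyte and mesenchyme genes (12 of 14 lower, camera adjusted p = 0.346) and smooth muscle and uterine epithelium genes (8 of 10, 0.0603) were not called. In each, 2 passed adjusted over the list alone. Angiogenic factors (adjusted p = 0.357), vascular tone genes (0.906) and collagens and matrix (0.43, 29 of 36 lower) were not called.

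Genes of mitochondria, ribosomes and the early stress response were lower. Immediate early genes, switched on within minutes of a stimulus, were lower for 19 of 21 (median -0.21, adjusted p = 0.00515, adjusted p = 0.169 with an estimated correlation, 0.00115 to 0.169 over the alternatives), and the call ended without control female 3 (0.0584). Ier3 stood at 99.2 ± 9.69 against 75.6 ± 10.2 FPKM (-0.39 ± 0.09), lower in all 9 of 9 pairs of both sexes, and Ccn2, a matrix and growth factor gene, at 234 ± 68.1 against 131 ± 51.5 FPKM. This was the 1 list called by limma's fry, which does not compare a list with other genes (adjusted p = 0.00381 for one direction, 0.0217 for either). By exact permutation of treatment within sex its list mean reached p = 0.005, the smallest 400 relabelings allow (adjusted p = 0.108). Relabelings here and below take placentas as separate, which shared dams would break. Pericyte and mesenchyme genes reached the same values and oxidative phosphorylation genes 0.025 (adjusted p = 0.358). The other 14 lists camera called had larger exact permutation p: sinusoidal giant cells 0.05, ribosomal proteins 0.075, spongiotrophoblast 0.13, unfolded protein response 0.14, endothelium 0.145, uterine natural killer cells 0.15, macrophages 0.2, pregnancy-specific glycoproteins 0.21, hypoxia 0.215, X-linked genes 0.26, giant cells 0.445, prolactin family 0.78, erythroid cells 0.805 and glucose transport 0.89 (lowest adjusted p = 0.392). Nuclear genes of oxidative phosphorylation were lower for 42 of 43, and for 37 and 36 with the other scalings (median -0.16, adjusted p = 0.000137, adjusted p = 0.78 with an estimated correlation, 1.03e-08 to 0.78 over the alternatives), with the complex I gene Ndufa8 lower in all pairs (35.5 ± 3.78 against 28.1 ± 2.62 FPKM). Ribosomal protein genes were lower for 73 of 78 but for 54 with median-of-ratios scaling and 56 with quantile normalization (median -0.12, adjusted p = 0.00263, adjusted p = 0.853 with an estimated correlation, 6.8e-09 to 0.853 over the alternatives). Their call ended with median-of-ratios scaling (0.362) and without control female 3 (0.538), estradiol female 3 (0.764) or estradiol male 1 (0.0501). Heat shock genes were lower for 13 of 15, or 10 of 15 with either other scaling, without a call (adjusted p = 0.157), and 2 passed adjusted over the list alone, the chaperone Hspa8 (689 ± 59.2 against 567 ± 36.3 FPKM) having the smallest p.

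None of the single genes chosen beforehand passed for estradiol averaged over sexes without library weights. Of the 26, for growth, hormones, transport, cell types and vessels along with the sex markers Ddx3y and Xist, 20 were tested and 6 had an unadjusted p under 0.05: Vegfa and Flt1 higher, and lower Sult1e1, the sulfotransferase that inactivates estrogens (64.8 ± 18.9 against 35.4 ± 21.1 FPKM, -1.01 ± 0.36), Cdkn1c, the imprinted growth inhibitor (464 ± 94.1 against 356 ± 86.4 FPKM, -0.39 ± 0.15), Kdr, and Igf1r, the receptor of insulin-like growth factors (4.28 ± 0.347 against 3.56 ± 0.534 FPKM). This held over all genes in limma and adjusted over the list alone (lowest adjusted p = 0.0613), but with array weights 4 passed over all genes: Flt1 (0.0256), Cdkn1c (0.0256), Igf2 (0.0388) and Kdr (0.0465). Igf2 stood at 904 ± 222 against 733 ± 252 FPKM (-0.33 ± 0.23), the glucose transporter Slc2a1 at 453 ± 115 against 446 ± 62.6 FPKM, and the estrogen receptor Esr1 at 1.67 ± 0.721 against 1.73 ± 1.15 FPKM. H19 and Xist are not listed, and Pgr, Hsd11b2, Gcm1 and Synb lay under the filter.

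Of the remaining lists, X-linked genes (6 of 8 higher, adjusted p = 0.00617, adjusted p = 0.305 with an estimated correlation, range 0.00436 to 0.401) and erythroid genes were called up. The X-linked list was 8 of 8 higher with either other scaling. For erythroid genes 5 of 12 were higher, with a median of -0.03 and a mean of 0.07, and 7 of 12 with median-of-ratios scaling (adjusted p = 0.0311, adjusted p = 0.78 with an estimated correlation, 0.00236 to 0.927 over the alternatives). The erythroid call ended with median-of-ratios scaling (0.361) and without control female 3 (0.249), control male 2 (0.0985), control male 3 (0.157), estradiol female 1 (0.112), estradiol female 2 (0.075), estradiol male 2 (0.0615) or estradiol male 3 (0.239). Not called were yolk sac endoderm (adjusted p = 0.161), estrogen-responsive genes (0.657), steroid synthesis (0.906), cholesterol synthesis (0.906), fatty acid uptake (0.901), amino acid transporters (0.151), imprinted genes (0.906), insulin-like growth factor signalling (0.906), interferon response (0.151), complement and coagulation (0.151), cell cycle (0.197), antioxidant response (0.906), apoptosis (0.906), ion and solute transport (0.351) and histones (0.151). Lymphocyte genes (0 of 10 listed past the filter), mitochondrially encoded genes (0 listed) and Y-linked genes (2 past the filter) were not tested. No list call for any of the 7 comparisons held with an estimated correlation (lowest adjusted p = 0.0972).

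**Figure D3:**
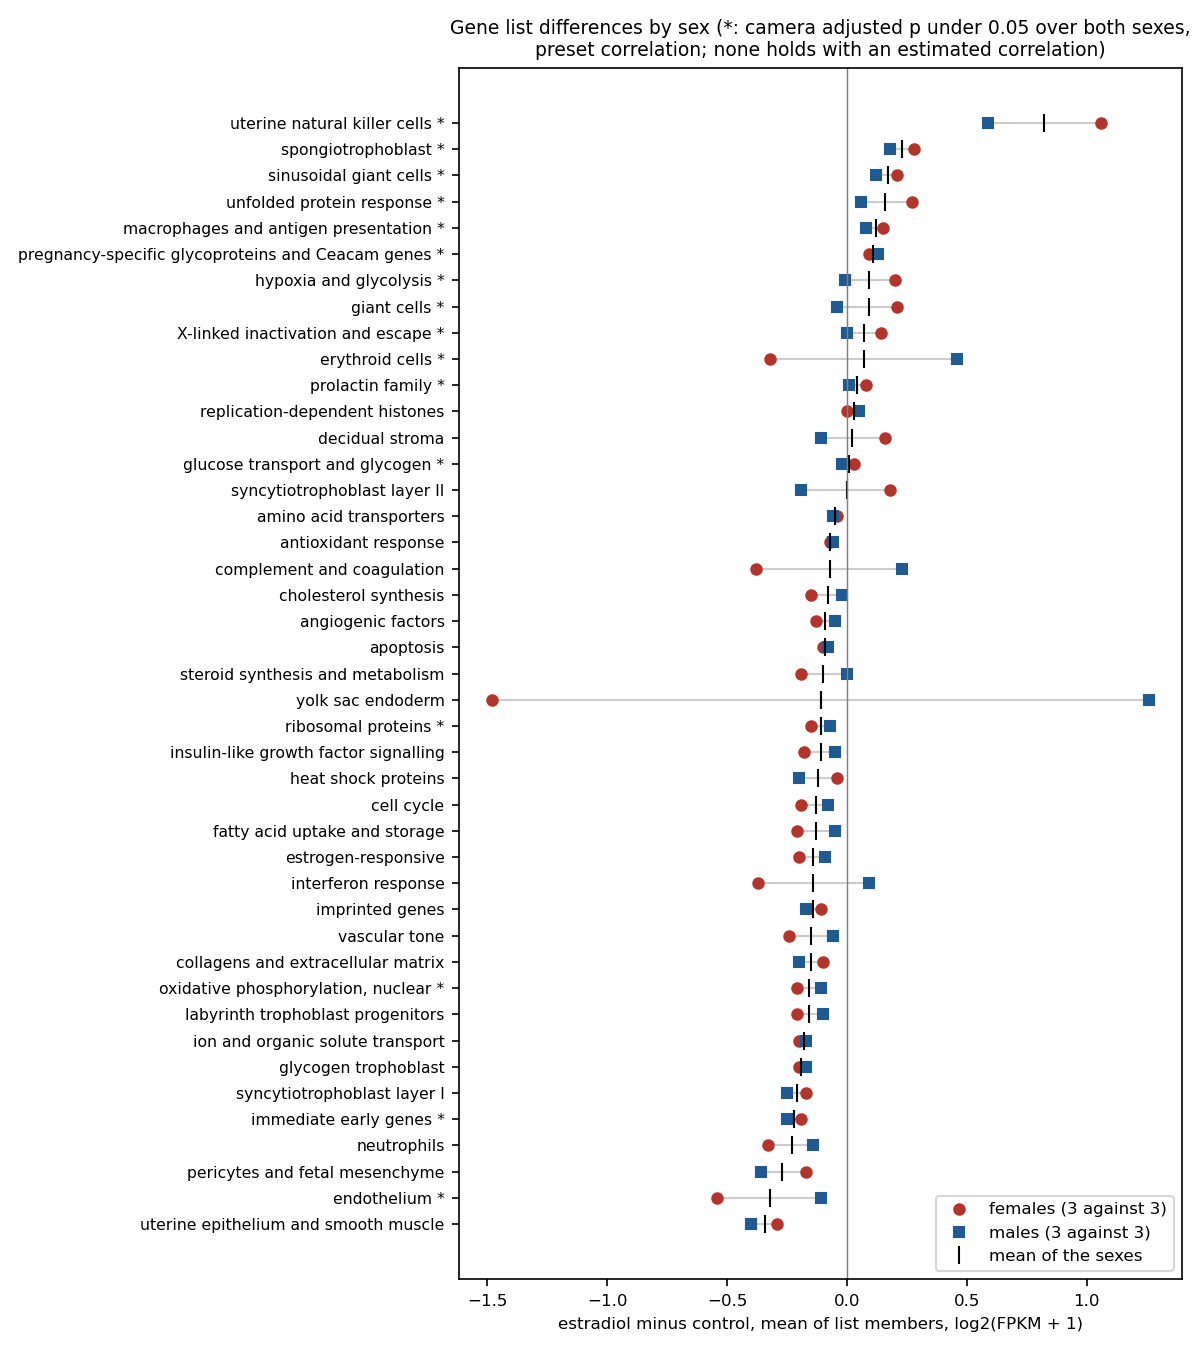
Estradiol minus control difference of each gene list (x axis, mean of members on log2(FPKM + 1)), with circles for 3 against 3 females, squares for 3 against 3 males, bars for their mean and asterisks for camera calls over both sexes. Uterine natural killer genes lie highest (0.82), and yolk sac genes part the sexes most (-1.48 in females, 1.26 in males).

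In female placentas Vegfa was higher and interferon response genes lower after estradiol. Vegfa stood at 23.1 ± 3.56 FPKM in 3 control and 41.9 ± 2.98 FPKM in 3 estradiol placentas (0.84 ± 0.20). Gbp2, an interferon-induced GTPase, stood at 14 against 7.24 FPKM (-0.87 ± 0.18) and the antiviral gene Oasl2 at 32.8 ± 3.1 against 20.6 ± 4.83 FPKM. Uggt1 was higher (25.7 ± 1.41 against 36.2 ± 2.61 FPKM, 0.47 ± 0.08), as was the mitochondrial carrier gene Slc25a48 (1.57 ± 0.448 against 3.17 ± 0.328 FPKM). Rnd1 (2.13 ± 0.498 against 0.801 ± 0.114 FPKM), the zinc transporter gene Slc30a3 (15 ± 1.28 against 8.49 ± 1.06 FPKM, -0.76 ± 0.14) and Psg22 (389 ± 6.58 against 155 ± 32.7 FPKM, -1.34 ± 0.28) were lower. None of these passed in limma (adjusted p = 0.454 for the 6 with the smallest p). Adjusted over the list alone, 1 of the 20 chosen genes passed (Vegfa, 0.0294). The count of passing genes was 0 by limma and 0 by voom, with 973 (202 higher, 771 lower) and 899 at an unadjusted p under 0.05. The limma count was 483 without control female 1, under the 546 due to chance, 1849 without control female 3 and 2355 with array weights, which passed 0 genes. With median-of-ratios scaling those were 515 higher and 399 lower, and with quantile normalization 600 and 389.

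Camera called 18 lists in females. Interferon response genes were lower for 24 of 26 (median -0.37, adjusted p = 7.37e-08, adjusted p = 0.421 with an estimated correlation, 1.12e-10 to 0.421 over the alternatives), and 6 passed adjusted over the list alone. Endothelial genes were lower for 19 of 20 (median -0.59, adjusted p = 8.31e-06, adjusted p = 0.625 with an estimated correlation, range 8.6e-08 to 0.625), with the tight junction gene Cldn5 at 11.4 ± 2.91 against 5.85 ± 0.601 FPKM. Higher were the unfolded protein response (21 of 24, adjusted p = 7.37e-08, adjusted p = 0.318 with an estimated correlation, range 5.8e-14 to 0.441), where the chaperone Hspa5 went from 846 ± 177 to 1320 ± 368 FPKM, hypoxia and glycolysis (20 of 27, adjusted p = 2.22e-07, adjusted p = 0.318 with an estimated correlation, range 3.81e-11 to 0.441), spongiotrophoblast (19 of 21, adjusted p = 2.5e-07, adjusted p = 0.574 with an estimated correlation, range 1.5e-15 to 0.574), uterine natural killer cells (7 of 8, adjusted p = 4.72e-05, adjusted p = 0.544 with an estimated correlation, range 1.02e-09 to 0.544), macrophages and antigen presentation (12 of 16, adjusted p = 0.000219, adjusted p = 0.318 with an estimated correlation, range 6.05e-05 to 0.441) and X-linked genes (8 of 8, adjusted p = 0.00303, adjusted p = 0.318 with an estimated correlation, range 0.00154 to 0.441). H2-Eb1, a class II antigen presenting gene, stood at 1.04 ± 0.344 against 2.04 ± 0.196 FPKM.

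The other female calls ended when a library was left out or with another scaling. With median-of-ratios scaling those of giant cells (0.0749), sinusoidal giant cells (0.0783), syncytiotrophoblast layer II (0.106), glucose and glycogen genes (0.051), prolactin genes (0.122) and pregnancy-specific glycoproteins (0.0535) ended. Giant cell genes were higher for 7 of 9 (adjusted p = 0.0048, adjusted p = 0.318 with an estimated correlation, range 0.000274 to 0.441). Without control female 2 (0.0998) or estradiol female 2 (0.313) the call ended. Layer II genes were higher for 7 of 9 (adjusted p = 0.026, adjusted p = 0.625 with an estimated correlation, range 0.00494 to 0.625). Without control female 3 (0.21), estradiol female 1 (0.0536) or estradiol female 2 (0.149) the call ended. Glucose and glycogen genes were higher for 12 of 20 (adjusted p = 0.0166, adjusted p = 0.615 with an estimated correlation, range 0.00951 to 0.615). Without control female 2 (0.093) or estradiol female 1 (0.0985) the call ended. Prolactin genes were higher for 16 of 23 (adjusted p = 0.00408, adjusted p = 0.687 with an estimated correlation, range 2.77e-07 to 0.687). Without control female 1 (0.163), control female 2 (0.216) or estradiol female 2 (0.619) the call ended. Pregnancy-specific glycoprotein genes were higher for 17 of 22 (adjusted p = 0.000559, adjusted p = 0.625 with an estimated correlation, range 5.26e-10 to 0.625). Without control female 1 (0.367) or estradiol female 2 (0.21) the call ended. Sinusoidal giant cells had 5 of 9 genes higher, or 4 of 9 with a median of 0 by quantile normalization (adjusted p = 0.00464, adjusted p = 0.318 with an estimated correlation, range 0.00195 to 0.441).

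Yolk sac genes were lower for 19 of 20 in females (median -1.49, adjusted p = 0.00572, adjusted p = 0.904 with an estimated correlation, range 5.48e-10 to 0.904), with scores from -1.35 to 2.75 in the 3 controls and from -1.78 to 0.65 in the 3 estradiol placentas. The call ended without control female 1 (0.509), control female 3 (0.366), estradiol female 2 (0.102) or estradiol female 3 (0.143). Cell cycle genes were lower for 14 of 17 (adjusted p = 0.0432, adjusted p = 0.888 with an estimated correlation, range 0.0146 to 0.888). The call ended without control female 1 (0.302), control female 3 (0.0612), control male 3 (0.0612), estradiol female 1 (0.184) or estradiol female 2 (0.102). Oxidative phosphorylation genes were lower for 42 of 43 (adjusted p = 8.31e-06, adjusted p = 0.625 with an estimated correlation, range 8.78e-12 to 0.625). Without estradiol female 3 (0.135) the call ended. Ribosomal protein genes were lower for 75 of 78 (63 and 54 with the other scalings, adjusted p = 4.72e-05, adjusted p = 0.888 with an estimated correlation, range 2.6e-14 to 0.921). Without control female 3 (0.471) or estradiol female 3 (0.921) the call ended. With 3 placentas against 3 the smallest exact p is 0.1, so no exact test was made within a sex.

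In male placentas Edn2 again had the smallest p. Edn2 stood at 13 ± 0.896 FPKM in 3 control and 2.8 ± 1.56 FPKM in 3 estradiol placentas (-1.97 ± 0.33, limma adjusted p = 0.796) and Eln at 26.2 ± 7.12 against 10 ± 4.59 FPKM (-1.35 ± 0.26). Aldh18a1 (14 ± 0.625 against 19.4 ± 0.302 FPKM), Enpp7 (15.1 ± 3.31 against 28 ± 2.3 FPKM) and the embryonic globin gene Hba-x (0.366 ± 0.0821 against 3.43 ± 1.2 FPKM, 1.66 ± 0.38) were higher, and the phosphatase gene Mtmr14 was lower (12.2 ± 0.274 against 9.13 ± 0.878 FPKM), all in 9 of 9 pairs. None passed in limma (adjusted p = 0.966 for these 5 genes). The count was 0 by limma and 0 by voom, with 472 (93 higher, 379 lower) and 449 genes at an unadjusted p under 0.05, where about 546 are due to chance. The limma count lay on either side of that number: 235 without control male 2, 726 without estradiol male 3 and 1888 with array weights, which passed 1 gene. With median-of-ratios scaling the 472 became 183 higher and 172 lower, and with quantile normalization 219 and 173. None of the 20 chosen genes passed adjusted over the list alone (lowest 0.697).

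Camera called 17 lists in males. Spongiotrophoblast genes were higher for 17 of 21 (median 0.21, adjusted p = 4.98e-08, adjusted p = 0.535 with an estimated correlation, range 3.93e-14 to 0.926) and pregnancy-specific glycoproteins for 16 of 22 (adjusted p = 5.26e-07, adjusted p = 0.535 with an estimated correlation, range 8.49e-11 to 0.926), with Psg25 at 574 ± 82.6 against 793 ± 98.6 FPKM. Erythroid genes were higher for 10 of 12 (median 0.47, adjusted p = 1.55e-07, adjusted p = 0.424 with an estimated correlation, range 3.2e-10 to 0.926), Hba-x passing adjusted over the list alone, and yolk sac genes for 20 of 20 (median 1.65, adjusted p = 4.03e-11, adjusted p = 0.535 with an estimated correlation, range 6.15e-23 to 0.926), of which Trf, the iron carrier transferrin, stood at 193 ± 21.1 against 422 ± 168 FPKM. Estradiol male 1 and 3 were the libraries with yolk sac scores above those of the male controls. Immediate early genes were lower for 18 of 21 (median -0.20, adjusted p = 0.00491, adjusted p = 0.225 with an estimated correlation, range 0.00288 to 0.225) and were the 1 list fry called (adjusted p = 0.0313), with Fosb at 2.22 ± 0.279 against 1.24 ± 0.403 FPKM. Smooth muscle and uterine epithelium genes were lower for 9 of 10 (adjusted p = 0.0154, adjusted p = 0.548 with an estimated correlation, range 2.31e-05 to 0.926), with the contractile actin gene Actg2 at 14.5 ± 7.55 against 5.48 ± 2.67 FPKM, a call that ended without control male 2 (0.0608), estradiol male 1 (0.0735) or estradiol male 2 (0.546). Heat shock genes were lower for 15 of 15, or 12 of 15 with either other scaling (adjusted p = 0.00491, adjusted p = 0.535 with an estimated correlation, range 0.000305 to 0.535), ending without control male 3 (0.139) or estradiol male 3 (0.245).

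The remaining male calls were up and each ended without at least 1 library. Interferon response genes were higher for 19 of 26 (median 0.10, adjusted p = 3.22e-05, adjusted p = 0.548 with an estimated correlation, range 3.41e-08 to 0.926). Without estradiol male 2 (0.881) or control male 1 (0.0757) the call ended. Complement genes were called up with 15 of 30 higher (median -0.01, mean 0.23, 18 of 30 with either other scaling, adjusted p = 0.00187, adjusted p = 0.535 with an estimated correlation, range 4.51e-07 to 0.926). Without estradiol male 1 (0.637) the call ended. Uterine natural killer genes were higher for 7 of 8 (adjusted p = 0.00288, adjusted p = 0.548 with an estimated correlation, range 6.91e-21 to 0.926). Without control male 1 (0.0925), estradiol male 1 (0.31) or estradiol male 2 (0.491) the call ended. Unfolded protein response genes were higher for 18 of 24 (adjusted p = 0.00427, adjusted p = 0.548 with an estimated correlation, range 1.01e-09 to 0.94). Without control male 1 (0.0757), control male 2 (0.728), estradiol male 1 (0.109) or estradiol male 2 (0.277) the call ended. Macrophage genes were called up with 7 of 16 higher (median -0.03, mean 0.08, 9 of 16 with either other scaling, adjusted p = 0.00427, adjusted p = 0.535 with an estimated correlation, range 1.1e-05 to 0.926). Without estradiol male 1 (0.109) or estradiol male 2 (0.392) the call ended, though C1qa stood at 6.58 ± 1.81 against 11.7 ± 0.381 FPKM. Sinusoidal giant cell genes (5 of 9 higher, adjusted p = 0.00495, adjusted p = 0.225 with an estimated correlation, range 0.00442 to 0.926) ended with median-of-ratios scaling (0.0591) and without estradiol male 3 (0.134).

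Hypoxia and glycolysis genes in males had 14 of 27 higher, a median of 0 and a mean of -0.01, 19 of 27 with either other scaling (called up, adjusted p = 0.0142, adjusted p = 0.548 with an estimated correlation, range 7.78e-07 to 0.984), and ended without control male 2 (0.755), control male 3 (0.099), estradiol male 1 (0.31) or estradiol male 2 (0.0541). Prolactin genes (11 of 23 higher, 16 with median-of-ratios scaling and 10 with quantile normalization, median -0.04, mean 0.01, adjusted p = 0.0133, adjusted p = 0.668 with an estimated correlation, range 1.89e-06 to 0.984) ended with median-of-ratios scaling (0.213) and without control male 1 (0.135), control male 2 (0.513), estradiol male 1 (0.458) or estradiol male 2 (0.881). Glucose and glycogen genes were called up with a median of -0.01 and a mean of -0.02, which became 0.07 and 0.06 with either other scaling (adjusted p = 0.0444, adjusted p = 0.548 with an estimated correlation, range 0.00426 to 0.997). They ended with median-of-ratios scaling (0.0634) and without control female 2 (0.0548), control male 2 (0.445), control male 3 (0.0947), estradiol male 1 (0.461) or estradiol male 2 (0.277). Angiogenic factors were called up with a median of -0.02 and a mean of -0.05, both above 0 with the other scalings (adjusted p = 0.0444, adjusted p = 0.548 with an estimated correlation, range 0.0396 to 0.984). They ended with median-of-ratios scaling (0.308) and without control female 2 (0.057), control female 3 (0.0551), control male 1 (0.0603), control male 3 (0.147), estradiol male 1 (0.109), estradiol male 2 (0.146) or estradiol male 3 (0.0761).

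No single gene passed the test of a different estradiol effect in the sexes. For the male minus female effect limma passed 0 genes (205 at an unadjusted p under 0.05, 135 higher and 70 lower, 161 and 119 with median-of-ratios scaling, 175 and 116 with quantile normalization) and voom 0 (175). Without control male 1 the 205 became 143, and without estradiol male 1 it became 327, under the 546 due to chance. With array weights it was 361, but with treatment and number as a random block 587, above that number. The smallest p belonged to Ahnak, a scaffold protein of the cell membrane (-0.97 ± 0.19), Ly6k (1.47 ± 0.35), Ndufaf5, an assembly factor of complex I (0.76 ± 0.18), Fat1 (-0.68 ± 0.16), Tmem252 (1.55 ± 0.38) and Angpt2, which destabilizes vessels (0.92 ± 0.23), with a limma adjusted p of 1 for each. Angpt2 stood at 19.5 FPKM in control females and 11.9 in control males. It was the 1 gene of the angiogenic list to pass adjusted over the list alone. Of the 20 chosen genes none did (lowest adjusted p = 0.743), and Vegfa differed by -0.67 ± 0.28.

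Interferon response genes parted the sexes most clearly among the lists. The estradiol effect in males exceeded that in females for 25 of 26 of them (mean 0.46, adjusted p = 1.98e-19, adjusted p = 0.527 with an estimated correlation, 2.17e-23 to 0.926 over the alternatives), with Rtp4 (0.84 ± 0.24), Xaf1 (0.54 ± 0.18) and Oasl2 (0.67 ± 0.23) leading. An exact permutation test of the list score gave p = 0.045, with an adjusted p of 0.948 over the 43 lists. No other list the interaction called had an exact permutation p under 0.13. Yolk sac genes differed for 19 of 20 (mean 2.74, adjusted p = 1.34e-14, adjusted p = 0.786 with an estimated correlation, range 3.25e-27 to 0.926), endothelial genes for 17 of 20 (mean 0.43, adjusted p = 2.14e-06, adjusted p = 0.786 with an estimated correlation, range 1.91e-10 to 0.926) and erythroid genes for 9 of 12 (mean 0.79, adjusted p = 5.15e-06, adjusted p = 0.786 with an estimated correlation, range 2.79e-08 to 0.926), each greater in males.

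The other 7 list calls of the interaction each ended without at least 1 library. Higher and lower here speak of the estradiol effect in males against that in females, not of levels. For layer II genes the effect was lower for 9 of 9 (mean -0.36, adjusted p = 0.0258, adjusted p = 0.786 with an estimated correlation, range 0.00027 to 0.926). The call ended without control female 3 (0.096), control male 1 (0.492), estradiol female 1 (0.0505), estradiol female 2 (0.144) or estradiol male 2 (0.0903). The effect on hypoxia genes was lower for 23 of 27 (mean -0.21, adjusted p = 0.00271, adjusted p = 0.786 with an estimated correlation, range 5.86e-06 to 0.926). Without control female 1 (0.0725), control male 1 (0.239) or estradiol female 2 (0.174) the call ended. The effect on unfolded protein response genes was lower for 21 of 24 (mean -0.21, adjusted p = 0.00396, adjusted p = 0.786 with an estimated correlation, range 3.9e-07 to 0.926). Without control female 2 (0.302), control male 3 (0.593), estradiol female 2 (0.539) or estradiol male 3 (0.205) the call ended. The effect on cholesterol synthesis genes was higher for 17 of 22 (mean 0.13, adjusted p = 0.0096, adjusted p = 0.872 with an estimated correlation, range 2.99e-05 to 0.926). Without control female 1 (0.505), control male 2 (0.195), estradiol female 3 (0.0762) or estradiol male 1 (0.171) the call ended. The effect on complement genes was higher for 22 of 30 (median 0.09, mean 0.61, adjusted p = 0.00396, adjusted p = 0.786 with an estimated correlation, range 1.02e-05 to 0.926). Without control female 3 (0.153) or estradiol male 1 (0.41) the call ended. The complement list shares 3 genes with the yolk sac list, and its score was highest in control female 1 (0.78, yolk sac 2.75) and estradiol male 1 (0.5, yolk sac 1.67). In estradiol male 3, whose yolk sac score was 1.78, it was -0.09. The effect on oxidative phosphorylation genes was higher for 37 of 43 (mean 0.10, adjusted p = 0.00332, adjusted p = 0.872 with an estimated correlation, range 7.08e-09 to 0.926). Without control female 3 (0.0559), estradiol female 3 (0.775) or estradiol male 2 (0.795) the call ended. The effect on ribosomal protein genes was higher for 67 of 78 (45 with quantile normalization, mean 0.08, adjusted p = 0.000956, adjusted p = 0.872 with an estimated correlation, range 4.16e-13 to 0.926). The call ended without control female 3 (0.575), estradiol female 3 (0.448) or estradiol male 2 (0.146).

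The female and male effects of estradiol were weakly alike. Across 10913 genes, which are not independent replicates, the effects correlated at r = 0.109 and rho = 0.286 (covariance 0.00527). The sexes share no control placentas, but same-numbered females and males of a treatment may share a dam (mean r = 0.26). Among genes at an unadjusted p under 0.05, 26 were higher in both sexes (1.72 by chance) and 131 lower (26.8). Genes that move together raise both counts, and shared dams could too. Without estradiol male 2 the correlation was -0.08, without control female 2 -0.06, and without estradiol male 3 it was 0.35.

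**Figure D4:**
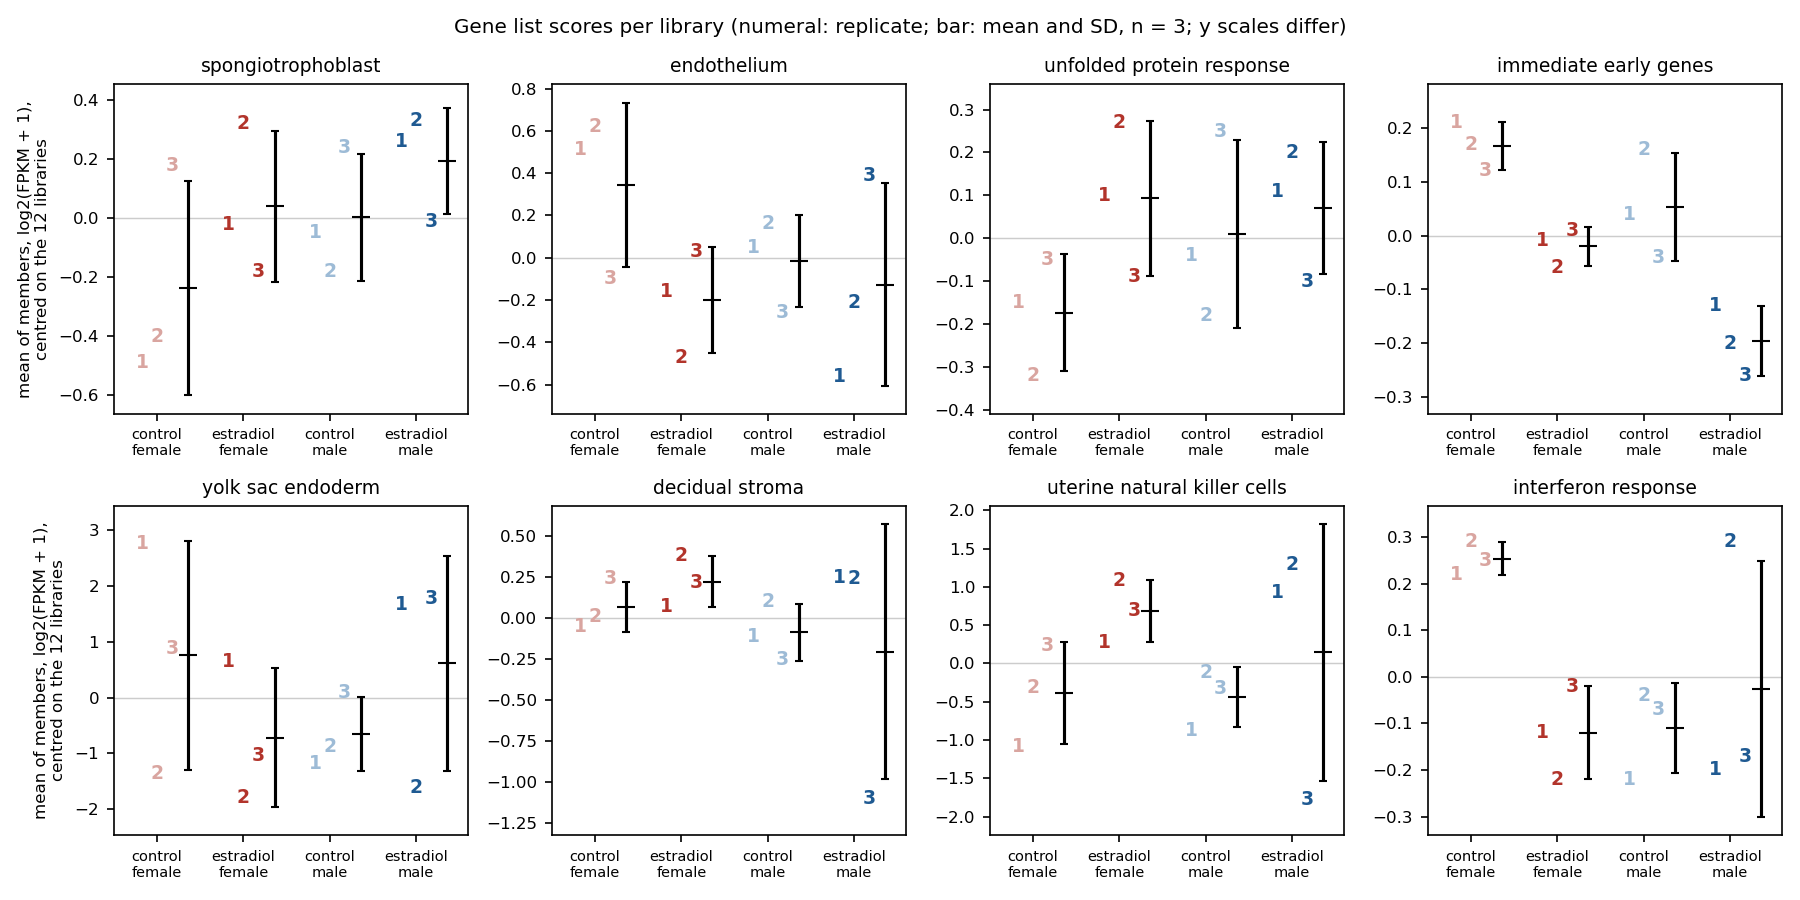
Scores of 8 gene lists (y axis, mean of members on log2(FPKM + 1), centred on the 12 libraries, with scales that differ) in the 4 groups (x axis), where numerals are single placentas by replicate and bars the mean and SD of 3. The yolk sac score runs from -1.78 to 2.75 across groups, and from -1.35 to 2.75 in control females, and estradiol male 3 lies lowest for decidual (-1.10) and natural killer genes (-1.78).

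Male and female placentas differed in Y-linked genes and, less firmly, in X-linked ones. Averaged over treatments, Ddx3y (0.0118 ± 0.0144 FPKM in 6 females, 6.56 ± 1.29 in 6 males, adjusted p = 6.76e-08) and Eif2s3y (0.013 ± 0.0305 against 2.47 ± 0.62 FPKM, adjusted p = 4.08e-05) rose in males by limma, the 2 genes of 10913 that passed. The X-linked genes Pin4, a prolyl isomerase (26.7 ± 4.08 against 16.7 ± 1.76 FPKM, -0.64 ± 0.11, adjusted p = 0.261), Taf1, a subunit of the basal transcription factor (5.66 ± 0.835 against 3.78 ± 0.336 FPKM, -0.47 ± 0.09, adjusted p = 0.42), and Rps4x (248 ± 27.6 against 191 ± 16 FPKM, -0.37 ± 0.07, adjusted p = 0.779) had the next smallest p without passing, as did Chac1 (1.45 ± 0.319 against 0.788 ± 0.225 FPKM, -0.46 ± 0.09, adjusted p = 0.779). Voom passed 2 genes as well. Where about 546 genes are due to chance, 530 had an unadjusted p under 0.05 (72 higher and 458 lower in males), but 219 higher and 109 lower with median-of-ratios scaling and 271 and 97 with quantile normalization. Without control male 3 the 530 became 272, without control female 3 it became 1191, with treatment and number as a random block 1355 and with array weights 2261. Of 371 X-linked genes tested 35 were lower and 2 higher, and of 10542 other genes 423 and 70.

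X-linked genes of inactivation and escape, the latter read from both X chromosomes in females, were lower for 7 of 8 in males (adjusted p = 8.48e-05, adjusted p = 0.0972 with an estimated correlation, range 6.06e-06 to 0.0972, fry adjusted p = 0.0212), and 4 passed adjusted over the list alone: Ogt, the nutrient-sensing sugar transferase (26.7 ± 4.54 against 19.1 ± 2.22 FPKM), Kdm5c (11.8 ± 1.82 against 8.42 ± 0.877 FPKM), Utp14a (4.07 ± 0.342 against 3.22 ± 0.178 FPKM) and Eif2s3x (16.5 ± 3.95 against 10.9 ± 1.53 FPKM). Spongiotrophoblast and Psg genes were higher in males: pregnancy-specific glycoproteins for 19 of 22 (median 0.24, adjusted p = 6.86e-19, adjusted p = 0.128 with an estimated correlation, range 1.45e-27 to 0.418) and spongiotrophoblast genes for 18 of 21 (median 0.23, adjusted p = 2.57e-16, adjusted p = 0.362 with an estimated correlation, range 6.55e-27 to 0.488), with Psg25 at 518 ± 165 against 684 ± 145 FPKM. Prolactin genes (15 of 23 higher, adjusted p = 1.12e-05, adjusted p = 0.635 with an estimated correlation, range 4.58e-11 to 0.684) lost their call with median-of-ratios scaling (0.0574), and sinusoidal giant cell genes (adjusted p = 0.000187, adjusted p = 0.0972 with an estimated correlation, range 9.45e-05 to 0.469) had 7 of 9 higher, but 4 of 9 with a median of 0 by quantile normalization. Unfolded protein response genes were higher for 20 of 24 (adjusted p = 7.03e-06, adjusted p = 0.585 with an estimated correlation, range 2.12e-10 to 0.684), a call that ended without control male 3 (0.0608).

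Giant cell genes were higher in males for 6 of 9 (adjusted p = 0.0161, adjusted p = 0.543 with an estimated correlation, range 0.000374 to 0.684), ending with median-of-ratios scaling (0.289) and without control female 2 (0.166), control male 3 (0.118), estradiol female 1 (0.0546), estradiol female 3 (0.2), estradiol male 1 (0.247) or estradiol male 2 (0.208). Antioxidant genes were lower for 20 of 21, or 17 and 16 with the other scalings (adjusted p = 0.0466, adjusted p = 0.925 with an estimated correlation, range 0.00501 to 0.925), ending with median-of-ratios scaling (0.0585) and without control female 3 (0.469), control male 1 (0.132), control male 3 (0.0668), estradiol female 2 (0.391) or estradiol male 3 (0.684). Ribosomal protein genes were lower for 78 of 78, but for 39 with median-of-ratios scaling and 32 with quantile normalization (adjusted p = 0.0137, adjusted p = 0.925 with an estimated correlation, range 2.26e-13 to 0.945), and the call ended with the first of these (0.684) and without control female 3 (0.945), control male 3 (0.0644), estradiol female 2 (0.536), estradiol male 1 (0.37) or estradiol male 3 (0.113).

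Within control placentas 2 genes passed in limma (1 in voom), Ddx3y (adjusted p = 4.36e-06) and Eif2s3y (adjusted p = 0.00153), with 406 at an unadjusted p under 0.05 (79 higher, 327 lower, but 249 and 143 with median-of-ratios scaling and 304 and 139 with quantile normalization). Without control male 3 the 406 became 189, without control female 3 it became 1046, and with array weights 1883. Tmem98 (5.6 ± 1.24 against 3.3 ± 0.46 FPKM), Xaf1 (11.6 ± 1.41 against 7.51 ± 0.337 FPKM), Angpt2 (19.5 ± 1.9 against 11.9 ± 1.19 FPKM) and Hebp1 (22 ± 2.17 against 15.1 ± 2.04 FPKM) followed without passing (adjusted p = 1). Camera called 14 lists. Interferon response genes were lower in males for 25 of 26 (adjusted p = 3.96e-11, adjusted p = 0.515 with an estimated correlation, range 1.59e-16 to 0.515), and 7 passed adjusted over the list alone. Endothelial genes were lower for 20 of 20, or 19 with either other scaling (adjusted p = 0.000213, adjusted p = 0.806 with an estimated correlation, range 9e-07 to 0.806). Spongiotrophoblast genes (19 of 21, adjusted p = 8.94e-10, adjusted p = 0.515 with an estimated correlation, range 1.87e-21 to 0.583) and pregnancy-specific glycoproteins (18 of 22, adjusted p = 7.1e-09, adjusted p = 0.515 with an estimated correlation, range 1.45e-18 to 0.583) were higher, as were sinusoidal giant cell genes (7 of 9, but 4 of 9 with a median of 0 by quantile normalization, adjusted p = 0.002, adjusted p = 0.295 with an estimated correlation, range 0.0014 to 0.583), whose call ended with median-of-ratios scaling (0.0614).

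The other 9 calls in control placentas ended without at least 1 library. Unfolded protein response genes were higher for 20 of 24 (adjusted p = 3.7e-07, adjusted p = 0.515 with an estimated correlation, range 1.92e-11 to 0.583). Without control male 3 (0.114) the call ended. Prolactin genes were higher for 15 of 23 (adjusted p = 0.000438, adjusted p = 0.746 with an estimated correlation, range 3.57e-10 to 0.749). The call ended without control female 1 (0.111), control female 2 (0.164) or control male 3 (0.438). Giant cell genes were higher for 6 of 9 (adjusted p = 0.00211, adjusted p = 0.515 with an estimated correlation, range 0.000342 to 0.583). Without control female 2 (0.116) or control male 3 (0.0631) the call ended. Median-of-ratios scaling ended the last 2 as well (0.0895 each). Erythroid genes were lower for 11 of 12 (adjusted p = 0.000642, adjusted p = 0.633 with an estimated correlation, range 8.43e-06 to 0.633). Without control male 2 (0.0506) the call ended. Yolk sac genes were lower for 20 of 20 (adjusted p = 0.000441, adjusted p = 0.806 with an estimated correlation, range 7.16e-15 to 0.806). Without control female 1 (0.346), control female 3 (0.256) or control male 1 (0.0528) the call ended. Complement genes were lower for 28 of 30 (adjusted p = 0.0047, adjusted p = 0.643 with an estimated correlation, range 1.39e-05 to 0.643). Without control female 3 (0.477) or control male 1 (0.0528) the call ended. Oxidative phosphorylation genes (42 of 43 lower, adjusted p = 0.000438, adjusted p = 0.806 with an estimated correlation, range 1.56e-05 to 0.806) and ribosomal protein genes (77 of 78 lower, but 36 with quantile normalization, adjusted p = 2.92e-05, adjusted p = 0.82 with an estimated correlation, range 1.68e-09 to 0.82) ended without control female 3 (0.0923 and 0.808). Cell cycle genes were lower for 15 of 17 (adjusted p = 0.0486, adjusted p = 0.82 with an estimated correlation, range 0.0144 to 0.82). Without control female 1 (0.346), control female 3 (0.0643), control male 1 (0.117), control male 2 (0.0506), control male 3 (0.073), estradiol female 2 (0.0592) or estradiol female 3 (0.0554) the call ended.

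Within estradiol placentas Ddx3y (adjusted p = 2.32e-06) and Eif2s3y (adjusted p = 0.0017, listed at 0 in all 3 estradiol females) passed in limma and 2 genes in voom, with 264 at an unadjusted p under 0.05 (36 higher, 228 lower, but 116 and 87 with median-of-ratios scaling and 160 and 79 with quantile normalization). Without estradiol female 1 the 264 became 140, without estradiol male 1 it became 580, and with array weights 601. Taf1 (-0.62), Pin4 (-0.69), Ogt (30.3 against 19.6 FPKM, -0.61) and Chac1 (-0.59) followed (adjusted p = 0.993). Of 11 lists called, X-linked genes were lower in males for 8 of 8, or 6 of 8 with either other scaling (adjusted p = 9.64e-06, adjusted p = 0.112 with an estimated correlation, range 3.25e-06 to 0.112, fry adjusted p = 0.0385), and 4 passed adjusted over the list alone. Pregnancy-specific glycoprotein genes were higher for 20 of 22 (adjusted p = 6.01e-13, adjusted p = 0.427 with an estimated correlation, range 1.17e-15 to 0.804) and yolk sac genes for 18 of 20 (adjusted p = 6.01e-13, adjusted p = 0.758 with an estimated correlation, range 3.61e-25 to 0.804).

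The other 8 calls in estradiol placentas ended without at least 1 library. Spongiotrophoblast genes were higher for 19 of 21 (adjusted p = 7.61e-08, adjusted p = 0.853 with an estimated correlation, range 3.1e-14 to 0.853). Without estradiol female 3 (0.064) the call ended. Interferon response genes were higher for 21 of 26 (adjusted p = 1.89e-07, adjusted p = 0.779 with an estimated correlation, range 2.14e-11 to 0.847). Without estradiol male 2 (0.847) the call ended. Endothelial genes were higher for 16 of 20 (adjusted p = 0.011, adjusted p = 0.924 with an estimated correlation, range 3.51e-06 to 0.924). Without estradiol female 2 (0.284) or estradiol male 3 (0.553) the call ended. Erythroid genes were higher for 10 of 12 (adjusted p = 0.00967, adjusted p = 0.884 with an estimated correlation, range 0.000564 to 0.884). Without estradiol female 3 (0.249), estradiol male 2 (0.0984) or estradiol male 3 (0.257) the call ended. Hypoxia genes were lower for 24 of 27 (adjusted p = 0.00812, adjusted p = 0.884 with an estimated correlation, range 8.46e-06 to 0.884). Without estradiol female 1 (0.061), estradiol female 2 (0.566) or estradiol male 3 (0.105) the call ended. Cholesterol synthesis genes were higher for 14 of 22 (adjusted p = 0.0014, adjusted p = 0.884 with an estimated correlation, range 0.000467 to 0.884). Without estradiol female 3 (0.0712) or estradiol male 1 (0.167) the call ended. Sinusoidal giant cell genes were higher for 6 of 9 (4 of 9 with a median of 0 by quantile normalization, adjusted p = 0.0436, adjusted p = 0.427 with an estimated correlation, range 0.0274 to 0.804). Without estradiol female 1 (0.0638), estradiol female 3 (0.205), estradiol male 1 (0.144) or estradiol male 3 (0.239) the call ended. Prolactin genes were higher for 14 of 23 (adjusted p = 0.011, adjusted p = 0.924 with an estimated correlation, range 1.34e-08 to 0.924). Without estradiol female 1 (0.126), estradiol female 3 (0.905), estradiol male 1 (0.469) or estradiol male 2 (0.847) the call ended. Median-of-ratios scaling ended the calls of erythroid (0.179), sinusoidal giant cell (0.179), endothelial (0.153) and prolactin genes (0.278).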

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

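Chosen after the result was seen were the scaling tests of the unfolded protein response and of endothelium, the correlation of the spongiotrophoblast and endothelium scores, the permutation test of opposite yolk sac effects and the depth of estradiol male 3. Flagged by the test of the difference between the sexes (camera, male minus female estradiol effect) were list means of 0.79 for erythroid genes, -0.36 for syncytiotrophoblast layer II, 0.43 for endothelium, 2.74 for yolk sac endoderm, 0.13 for cholesterol synthesis, -0.21 for hypoxia and glycolysis, -0.21 for the unfolded protein response, 0.46 for interferon response, 0.61 for complement and coagulation, 0.10 for oxidative phosphorylation and 0.08 for ribosomal proteins. None held with an estimated correlation (lowest adjusted p = 0.527). Ahnak (-0.97), Ly6k (1.47) and Tmem252 (1.55) moved one way in every female pair and the other way in every male pair, a separation that was not tested as such. In all, 13 of 10913 genes separated so, where 54.6 would by chance.

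Chance splits of the placentas gave as many genes at an unadjusted p under 0.05 as the real groups in 12 of 100 splits for estradiol averaged over sexes (1354 genes, highest other 2364), in 76 of 100 for the interaction (205, highest other 3390) and in 30 of 100 for sex (530, highest other 4195). Splits with far more genes than the real groups point to structure among the placentas that is neither treatment nor sex. With 10 splits the shares cannot fall under 0.05: 3 of 10 in females (973, highest other 2179), 5 of 10 in males (472, highest other 1584), 3 of 10 between sexes in control (406, highest other 2137) and 6 of 10 in estradiol placentas (264, highest other 2631).

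Spongiotrophoblast and unfolded protein response genes were higher and endothelial genes lower after estradiol. Random assignment fits this: 32 of 100 splits called as many lists (16 real, highest other 22). A different balance of junctional zone and labyrinth between pieces fits as well: within groups the spongiotrophoblast and endothelium scores correlated at r = -0.87 (exact p = 0.0054, rho = -0.85 with exact p = 0.00849, r = -0.81 without the 2 farthest, adjusted p = 0.00945 over 7 relations). Scaling by a few abundant genes predicted a within-group r below 0 between the unfolded protein response and spongiotrophoblast scores. The r was 0.84 (exact p = 0.00309, rho = 0.79 with exact p = 0.00694, r = 0.86 without the 2 farthest, adjusted p = 0.00945), against that prediction. A varying balance of tissues would give a high r as well, so it cannot show whether scaling also shifts the list. For endothelium scaling cannot be told apart, as the difference stayed under 2 standard errors from 0 with median-of-ratios scaling (-0.25 ± 0.16) and as deposited (-0.32 ± 0.20), though 19 of 20 genes were lower in both. With both scores as covariates the unfolded protein response difference was 0.025 ± 0.071 instead of 0.163 ± 0.102, and the 15.6% kept fits that balance by the bound set beforehand, although values above the bound lie within the standard error. An effect of estradiol on these genes or on the size of the layers stays open and was not tested.

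Yolk sac genes differed up to 23-fold between libraries, with scores from -1.35 to 2.75 in control females and from -1.18 to 0.1 in control males. Yolk sac tissue carried into some pieces fits: a second endoderm list without shared genes followed the first at r = 0.93 within groups (exact p = 0.000772, the smallest of 1296 rearrangements, rho = 0.88 with the same p, r = 0.89 without the 2 farthest). The lists cannot tell yolk sac from other endoderm. An opposite estradiol effect in the sexes cannot be told apart by exact permutation (p = 0.145).

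Decidual and natural killer genes were lowest in estradiol male 3. Less maternal decidua in that piece fits, since a second decidual list stood at -0.71 there and between -0.13 and 0.25 in the other 11. Lower depth was argued against (38.99 M recovered reads). A biological explanation was not tested for a single placenta.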

How the results depend on the processing

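No gene list call held with an estimated correlation. Fry called 1 list each for estradiol averaged and in males, and between sexes averaged and in estradiol placentas, and 0 otherwise. Exact permutation of list means called 0 for the averaged effect. Without the 2 doubted libraries 14 lists were called between the sexes averaged. In males 10 to 19 lists were called as single libraries were left out. The cause of these changes was not tested, nor of those below unless stated.

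For estradiol averaged over sexes, array weights passed 1110 genes, the fit without the 2 doubted libraries 3, yolk sac and decidual scores as covariates 1, unadjusted p with a log2 difference of at least 1 12, and leaving out single libraries 0 to 5. Edn2 had an adjusted p of 0.015 with array weights, 0.0378 without the 2 doubted libraries, 0.0296 with covariates, 0.0497 without estradiol male 1 and 0.0314 without estradiol male 3, in a range of 0.015 to 0.721. Eln had 0.0378 without the 2 doubted libraries and 0.0193 without estradiol male 3 (0.015 to 0.721), and Prf1 0.0378 and 0.0314 (0.0265 to 0.726). Unadjusted p with a log2 difference of at least 1 passed 23 genes in females, 15 in males, 34 for the interaction, 7 between sexes in control and 11 in estradiol placentas. Array weights passed 1 gene in males (Eln, 0.0473).

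Between the sexes, no filter passed 4 genes averaged, 4 in control and 4 in estradiol placentas, and a mean FPKM of at least 5 passed 0, 0 and 0, because Ddx3y and Eif2s3y then drop out. Treatment and number as a random block passed 4 genes averaged, Pin4 (0.0171) and Taf1 (0.0285) being the added ones. Voom passed 1 gene in control placentas, where Eif2s3y had 0.0547, and the fit of the compared groups alone passed 1 in estradiol placentas, where it had 0.195.

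The replicate number was not taken to pair the placentas, and whether it marks a shared dam is not known. Same-numbered control and estradiol placentas correlated in their deviations at 0.52, -0.17 and -0.31 in females and -0.36, 0.06 and -0.09 in males, and with the number as a block 1 gene passed for the averaged effect (Edn2, 0.0488). Same-numbered females and males of a treatment correlated at 0.16, 0.04 and 0.45 in control and 0.09, 0.56 and 0.28 in estradiol placentas, 0.26 on average, and 2 of 36 matchings reached that. As a random block of treatment and number the consensus correlation was 0.41.

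Directions of small estradiol effects averaged over sexes turned. Esr1 was 0.02 with median-of-ratios scaling, 0.05 with quantile normalization, 0.06 with array weights, 0.14 without the 2 doubted libraries and -0.20 to 0.16 with single libraries left out. Syna was 0.02, 0.03 with the first 2 and -0.34 to 0.18 with libraries left out. Prl8a2 was 0.03 with array weights, 0.21 without the 2 doubted libraries and -0.40 to 0.20 with libraries left out, and Slc2a1 -0.08, -0.01 and -0.10 to 0.14. Hsd17b2 was -0.06 with array weights, Slc2a3 0.04, Ddx3y 0 and Rlim -0.01 without the 2 doubted libraries, and Slc38a4 0.02 with quantile normalization. With libraries left out Cyp11a1 ran from -0.07 to 0.25, Pgf from -0.01 to 0.51, Ddx3y from 0 to 0.13, Ahsp from -0.47 to 0.01 and Gata1 from -0.57 to 0.01. Prl3b1 was 0 with quantile normalization averaged, in females, in males and between the sexes, since it ranks highest in every library. In males Cts6 was -0.01 with array weights, -0.09 without the 2 doubted libraries and -0.09 to 0.40 with libraries left out, and Gzmb ran from -0.02 to 1.16. Between the sexes Cts6 was -0.03 with quantile normalization, -0.03 with array weights and -0.04 with covariates.

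Some list directions turned. Angiogenic factors in males had a fry adjusted p of 0.984. With libraries left out the adjusted p of ribosomal proteins ran from 2.6e-14 to 0.921 in females, 4.16e-13 to 0.575 for the interaction and 2.26e-13 to 0.945 between the sexes, and that of interferon response in males from 3.41e-08 to 0.881. Endothelium between the sexes in estradiol placentas had 0.576 without the 2 doubted libraries and 3.51e-06 to 0.553 with libraries left out. The correlation of female and male effects then ran from -0.08 to 0.35. Of the named-gene values 11387 kept their label, 82 were stronger, 2 weaker and 49 reversed, and of the list values 1417, 0, 400 and 7.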

Other observations

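Chosen after the result was seen was the grouping of the genes below, which were members of lists fixed beforehand and were not tested as groups of their own. These single genes had lower values after estradiol in 6 against 6 placentas: Acta2, the actin of smooth muscle (60.7 ± 16.5 against 33.7 ± 7.62 FPKM, -0.82 ± 0.18), Tagln (39.8 ± 10.6 against 20.7 ± 6.44 FPKM, -0.93 ± 0.21), Actg2 (15 ± 4.87 against 8.08 ± 4.14 FPKM, -0.89 ± 0.25), Cnn1 (2.81 ± 0.961 against 1.49 ± 0.597 FPKM), Myh11 (5.38 ± 1.19 against 3.66 ± 1.23 FPKM) and Fbln5, which assembles elastic fibers (3.95 ± 0.945 against 2.55 ± 0.508 FPKM). The first 3 were lower in 9 of 9 pairs of both sexes. None passed over all genes in limma (adjusted p = 0.217 for Acta2), and camera called none of the lists they came from (adjusted p = 0.346, 0.0603 and 0.43 for pericytes, smooth muscle and matrix).

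Single genes of vascular tone and of insulin-like growth factor signalling, lists that were not called (adjusted p = 0.906 each), had these values. Nppc, the C-type natriuretic peptide, was higher (6.57 ± 1.39 against 13 ± 4.48 FPKM, 0.83 ± 0.19) and Nppb, its B-type relative, lower (59.6 ± 22.5 against 30 ± 10.9 FPKM, -1.01 ± 0.33). Ece1, which activates endothelins, was lower (26.2 ± 6.33 against 19.2 ± 4.19 FPKM). Pappa2, a protease that frees insulin-like growth factors, was higher in 9 of 9 pairs of both sexes (279 ± 49.6 against 348 ± 32.8 FPKM, 0.33 ± 0.08), and the binding proteins Igfbp7 (261 ± 45.1 against 186 ± 36.8 FPKM) and Igfbp6 (38.1 ± 11 against 23.2 ± 5.74 FPKM) were lower. None passed over all genes in limma (adjusted p = 0.217 for Nppc and Pappa2).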
